A study of Mus musculus with 22 samples.

How the data were processed

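RNA from the terminal ileum of NOD mice, an inbred strain that develops autoimmune diabetes, was measured on 22 arrays of 1 colour, each holding 1 sample. The labels give a treatment (control, STAT or PAT) and a sex for every array, which makes 6 groups: 3 control females, 3 PAT females, 3 STAT females, 5 control males, 5 PAT males and 3 STAT males. PAT stands for antibiotics given as therapeutic doses in pulses and STAT for antibiotics at a sub-therapeutic level, per the labels. The drugs, doses, ages and scan dates are not given in the sources used here. RNA was extracted with TRIzol and cleaned on RNeasy columns, then labelled with biotin by an Affymetrix in vitro transcription kit, per the labels' protocols. Each array has its own title number and no number is shared, but nothing in the labels says that the samples came from separate animals. The p-values therefore measure only the spread between these samples, which may in part be technical.

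The deposited values are log2 expression values per probe set, and the authors made them with RMA in the affy package, per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises the probes of a probe set. The versions of both and any later step are not given in the sources used here. The deposited table held 45101 probe sets and no missing value. The column medians lay between 5.68 and 5.79, so the scale is log2 and the columns had been brought to nearly the same level. A log2 difference of 1 is a 2-fold change. RMA gives no detection calls, and background at low intensity pulls values together, so fold changes of dim genes are understated. The precision of every value here is limited by the number of arrays. No pair among the 231 pairs of arrays held identical values, and correlations between arrays ran from 0.982 to 0.997.

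Probe sets were named through the platform annotation that accompanied the data. Of the probe sets, 64 were controls of the array maker and were left out of the gene tests, 34945 had exactly 1 gene symbol, 932 had several and 9160 had none. A probe set with several symbols or none was not named. Where a gene had more than 1 probe set, as 9010 genes did, the probe set with the highest mean over all arrays stood for it. This left 18193 genes. Of 595 pairs of a named gene and a comparison, 249 had more than 1 probe set. In 198 of these every probe set moved in the same direction, and in 0 of them did another probe set pass the limma test in the opposite direction. The array maker's beta-actin and Gapdh control probe sets for the 3-prime and 5-prime ends of the transcripts gave a measure of RNA integrity per array, as the log2 difference of the ends.

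Differential expression was tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 22 arrays, so that the groups shared 1 estimate of the spread with 16 residual degrees of freedom, to which the empirical Bayes step added 4.88. Contrasts compared PAT and STAT with control within each sex and averaged over the sexes, PAT with STAT within each sex, females with males among controls, and the female with the male effect of PAT and of STAT (the interaction). P-values were adjusted by the Benjamini-Hochberg method over all genes within a contrast, and a gene was called at an adjusted p under 0.05. All adjusted p-values of genes come from this limma model and are two-sided. Errors beside log2 fold changes are standard errors (SE) of that model, and errors beside group levels are standard deviations (SD).

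Gene lists for 17 pathways and 20 cell types of the gut, 37 in all, held 491 genes, of which 438 were measured and 0 were in more than 1 list. The lists were tested with limma's camera, which asks whether the members of a list rank higher or lower than the other genes, with an inter-gene correlation preset at 0.01 and p-values adjusted over the 37 lists. Camera with an estimated correlation is far stricter, and of 98 list calls it kept 1, that of the sex-linked genes. Fry, limma's rotation test of whether a list moves on balance in 1 direction, kept 10. For each list the called members were counted over all genes and also with p-values adjusted over the list alone.

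The groups, the model, the lists, the choice of probe set and the alternatives were fixed before the data were examined, as was the rule for the genes named. The rule took, per comparison, the 10 called genes with the largest rise and the 10 with the largest fall among genes with a mean of at least 6 in the brighter group, and up to 4 members with the smallest p of each called list. It added every measured member of the epithelial defence list in the comparisons with controls. Where fewer than 5 genes were called, it took the 5 genes with the smallest p.

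The alternatives were the mean of a gene's probe sets, every probe set on its own, only genes with a mean of at least 6, quantile normalization repeated, columns centred on their medians, only the groups compared, a variance prior with trend and robust estimation, array weights, a term that splits the title numbers into low and high, a minimum of 1.5-fold, and each array left out in turn. After the data were seen, further runs were added: without PAT female 1 and PAT male 5, without STAT males 2 and 3, with the actin or the Gapdh difference as a covariate, and the list tests with each array left out in turn. The pairs of arrays were chosen because they stood apart from their groups. Without STAT males 2 and 3 the group holds STAT male 1 alone, and the model takes its spread from the other groups. A gene that changed sign without being called under either setting was counted as unmoved, which applied to 261 of the values.

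The model was tested on simulated data with normal noise around the real mean of each of the 18193 genes, at that gene's real residual spread, with 200 genes changed per comparison. Of genes changed 1.5-fold and 2-fold, it recovered 77% and 96% for PAT against control in males, 63% and 92% for PAT in females, 76% and 93% for STAT in males, and 58% and 95% for STAT in females. In these 4 runs it also called 2, 6, 10 and 13 unchanged genes in the same order, which is over 5% of the calls for STAT in males and in females. Over 11 simulated comparisons without change it called 1 gene, and of the 37 lists it called 1, the list that had been changed. The noise was drawn independently for every gene and array. The simulation therefore cannot show the rate of false calls, of genes or of lists, where genes are correlated or arrays share deviations. Other computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.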

Results

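The arrays separated by sex in the way the labels say. Xist, the RNA that silences an X chromosome, was at a mean log2 level of 12.39 in control females and 6.79 in control males, and the Y-linked Eif2s3y at 3.68 and 9.19. Column medians lay between 5.68 and 5.79. The first principal components held 20.08% and 18.88% of the variance. The first was highest in STAT males 2 and 3 (27.774 and 28.62) and in PAT female 1 (25.207). STAT males 2 and 3 also had the largest difference between the 3-prime and 5-prime ends of beta-actin, 0.59 and 0.60, against 0.28 to 0.42 in the other 20 arrays. The same difference for Gapdh, a second measure of RNA integrity, was -0.04 and -0.08 in them, above STAT male 1 (-0.25) and all 5 control males (-0.26 to -0.2), and -0.03 in PAT female 1 and -0.08 in PAT male 5. It was higher with PAT, at -0.16 ± 0.06 (SD) in PAT males and -0.24 ± 0.03 in control males, and -0.07 ± 0.04 and -0.15 ± 0.06 in females. Titles of STAT males 2 and 3 carry higher numbers than that of STAT male 1.

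**Figure D1:**
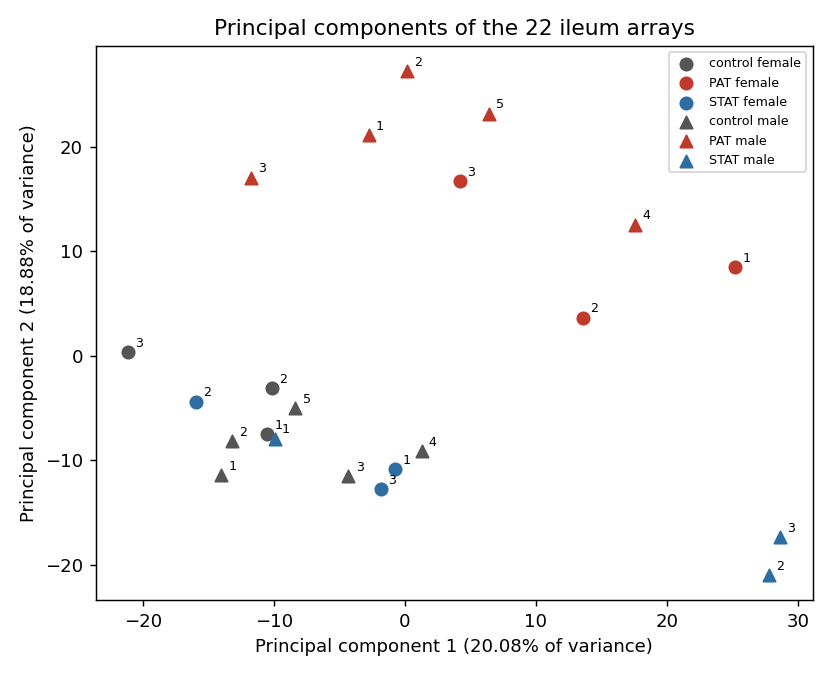
First 2 principal components of the 22 arrays. Grey marks control, red PAT and blue STAT; circles are females, triangles males, and the numbers are the replicates within a group.

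In mice given PAT, averaged over the sexes, the small GTPase Rab30 rose most, by 4.06 ± 0.27 on the log2 scale (16.7-fold, adjusted p = 1.3e-08), and every one of the 8 PAT arrays lay above every one of the 8 control arrays. Fgf15, the ileal hormone that limits bile acid synthesis in the liver, rose by 2.16 ± 0.52 (4.48-fold), the phosphatase Dusp14 by 2.15 ± 0.29 (4.44-fold), the plasminogen activator Plat by 1.84 ± 0.19 and the activin inhibitor Fst by 1.83 ± 0.18. The acute phase gene Saa1 fell by 3.99 ± 0.67 (15.9-fold, adjusted p = 0.00073), G6pc, which encodes a glucose-6-phosphatase, fell by 2.73 ± 0.28 (6.62-fold, adjusted p = 4.8e-06), and Retnlb fell by 2.85 ± 0.80 (7.23-fold, adjusted p = 0.024). The Saa1 value was -3.22 without PAT female 1 and -4.75 without PAT female 2, and stayed called. Saa2 (-1.64 ± 0.32), the interferon-induced Ifit1 (-1.60 ± 0.31) and the granzyme Gzma (-1.58 ± 0.24) fell as well. Limma called 1999 of 18193 genes, 839 higher and 1160 lower, of which 323 changed at least 1.5-fold, and 3287 probe sets when each was tested on its own. Of 45 named genes that were called, 32 stayed so whichever of the 16 arrays was left out. Retnlb was no longer called without control female 2, control female 3 or PAT female 1, with adjusted p up to 0.085. With the Gapdh difference as a covariate limma called 756 genes, 645 of them among the 1999. All 1999 kept their sign, with a median size of 0.30 against 0.35 and errors 1.19 times as large, so that a lost call can come from either. Rab30, Dusp14, Plat, Fst, Saa1, G6pc, Ifit1 and Gzma were called there, and Fgf15 (1.93 ± 0.64, adjusted p = 0.1), Retnlb (-1.61 ± 0.84, adjusted p = 0.36) and Saa2 (-1.0 ± 0.31, adjusted p = 0.075) were not. Of the log2 change 89.1% was kept for Fgf15, 56.3% for Retnlb and 60.9% for Saa2.

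**Figure D2:**
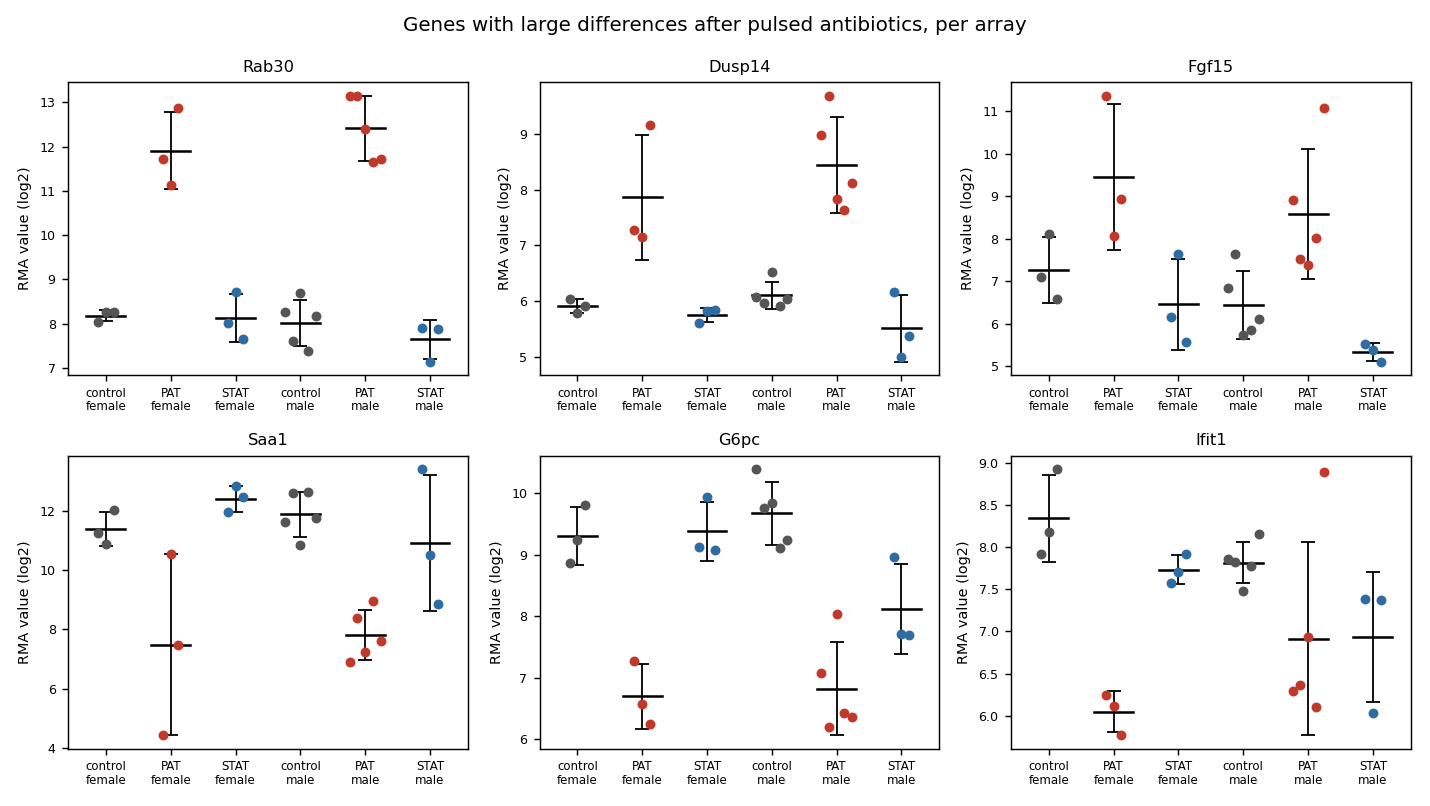
Log2 levels of Rab30, Dusp14, Fgf15, Saa1, G6pc and Ifit1 in each array. Points are arrays, lines are group means and bars are SD; groups hold 3 arrays, or 5 for control males and PAT males.

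Genes of the endoplasmic reticulum stress response ranked higher in PAT mice. Of 13 measured members 9 were higher, 0 lower and 4 not called, and 11 were higher when adjusted over the list alone. The chaperone Hspa5 rose by 0.46 ± 0.07, Dnajb9 by 0.85 ± 0.14, Creld2 by 0.77 ± 0.13 and Manf by 0.42 ± 0.08. The list's median was 0.417 and its camera adjusted p was 1.7e-09, and 0.2 with an estimated correlation.

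Interferon response genes ranked lower. Of 24 members 0 were higher, 10 lower and 14 not called, and 15 were lower when adjusted over the list alone. Oasl2 fell by 1.13 ± 0.21, Psmb8 by 0.77 ± 0.13, Psmb9 by 0.50 ± 0.08 and the RNA sensor Ddx58 by 0.47 ± 0.08. The median was -0.421 (camera adjusted p = 3.23e-07, and 0.644 with an estimated correlation). The camera calls of this list and of the endoplasmic reticulum stress list held whichever array was left out. By sex the interferon list was called in females (median -0.538) and not in males (-0.221, camera adjusted p = 0.0533), where its mean level was 0.736 in PAT male 5 and at most 0.303 in control males. Ifit1 was at 8.89 in PAT male 5, above every control male, and did not pass in males (-0.90).

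Epithelial defence genes ranked lower in PAT mice, with 1 of 17 higher, 7 lower and 9 not called, and 1 higher and 9 lower when adjusted over the list alone. Besides Saa1, Saa2 and Retnlb, the bactericidal lectins Reg3g (-0.66 ± 0.11, adjusted p = 0.00051) and Reg3b (-0.25 ± 0.07, adjusted p = 0.015) fell, as did the chemokine Ccl28 (-0.40 ± 0.09) and the antibody transporter Pigr (-0.25 ± 0.07). Sprr1a, which encodes a squamous envelope protein, rose by 1.57 ± 0.42 (adjusted p = 0.02). Values for Reg3a (-0.34), Saa3 (-0.83), Fut2 (-0.63), Tlr2 (-0.30), Duoxa2 (-0.19), Cxcl1 (-0.06), Nos2 (0.00), Lcn2 (0.05) and Il18 (0.19) did not pass. The median was -0.304 (camera adjusted p = 7.93e-04, and 0.644 with an estimated correlation). The list was called in males and not in females (median -0.263, camera adjusted p = 0.0508), where Ccl28 (-0.14), Pigr (-0.02) and Sprr1a (0.86) did not pass. Sprr1a in females was at 0.22 without PAT female 3. The Reg3b call ended without PAT female 1 (adjusted p = 0.051), the Sprr1a call without control female 3 or PAT female 3 (up to 0.068), and the Pigr call without control female 1, control female 2 or PAT female 3 (up to 0.061). With the Gapdh difference as a covariate Reg3g stayed called, and Ccl28 (-0.38 ± 0.12, adjusted p = 0.073), Reg3b (-0.19 ± 0.08, 0.2) and Pigr (-0.24 ± 0.09, 0.14) did not.

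Immediate early genes and endothelial genes ranked higher in PAT mice, the former called in males and not in females (median 0.318, camera adjusted p = 0.234) and the latter in females and not in males (0.096, 0.594). Of 10 immediate early genes 4 were higher and 0 lower (5 and 0 over the list alone), among them Egr1 (1.79 ± 0.40) and Dusp1 (1.25), with a median of 0.47 (camera adjusted p = 0.00187, and 0.644 with an estimated correlation). The Dusp1 call ended without control female 3 or PAT female 3 (adjusted p up to 0.078). Of 8 endothelial genes 3 were higher and 0 lower (6 and 0 over the list alone): the receptor Kdr (0.42 ± 0.11), Plvap (0.49 ± 0.14) and Lyve1 (0.27 ± 0.08), with a median of 0.285 (camera adjusted p = 0.00248, and 0.644 with an estimated correlation). The Kdr call ended without PAT female 1 or control female 3 (up to 0.061), and Plvap and Lyve1 were lost in 5 and 9 of the 16 runs that each left out 1 array (up to 0.11 and 0.12). None of these 3 was called with the Gapdh difference as a covariate, with smaller folds and larger errors (0.29 ± 0.12, 0.38 ± 0.17 and 0.21 ± 0.10, adjusted p = 0.23, 0.25 and 0.31).

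Of 20 cell division genes 2 were higher, Mcm3 (0.58 ± 0.14) and Rrm2 (0.54 ± 0.18), and 1 when adjusted over the list alone, with a median of 0.136 (camera adjusted p = 0.00382, and 0.83 with an estimated correlation). The sexes went opposite ways, with a median of 0.503 in females, where the list was called, and -0.188 in males, where it was not (camera adjusted p = 0.262). Rrm2 was lost in 13 of the 16 runs (adjusted p up to 0.13). Of 9 bile acid genes 4 were higher and 0 lower (4 and 0 over the list alone): Fgf15, the receptor Nr0b2 (1.59 ± 0.36), the transporter Abcc2 (1.42 ± 0.22) and the binding protein Fabp6 (0.21 ± 0.07), which was lost in 11 runs (up to 0.13). The bile acid median was 0.202 (camera adjusted p = 0.0176, and 0.644 with an estimated correlation), and the list call ended without PAT female 3 (0.097) and was not made in females alone (median 0.209, camera adjusted p = 0.234). The B cell and follicle list had 14 members, with 1 higher, Cxcl13 (0.72 ± 0.23), and 0 over the list alone (median 0.167, camera adjusted p = 0.0333, and 0.83 with an estimated correlation). That list call ended without PAT female 1 (0.89), control female 1 (0.081) or control male 4 (0.053) and was not made in males (median 0.033, camera adjusted p = 0.655), and Cxcl13 was lost in 13 runs (up to 0.12). With the Gapdh difference as a covariate Mcm3 (0.48 ± 0.17, adjusted p = 0.13), Rrm2 (0.39 ± 0.21, 0.36), Nr0b2 (1.29 ± 0.42, 0.093) and Cxcl13 (0.54 ± 0.27, 0.34) were not called, with smaller folds and larger errors, nor was Fabp6 (0.21 ± 0.08, 0.2), whose fold stayed.

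In males alone PAT raised Rab30 by 4.39 ± 0.34 (21-fold, adjusted p = 1.4e-07, 5 arrays against 5), Flrt3 and Dusp14 by 2.35 ± 0.34 and 2.35 ± 0.36, Maff by 2.23 ± 0.28 and Zfand2a by 2.04 ± 0.27. Saa1 fell by 4.07 ± 0.82 (16.8-fold), from a level of 11.89 ± 0.75 (SD) in controls to 7.82 ± 0.84. G6pc fell by 2.85 ± 0.34 (7.2-fold), the endothelin gene Edn2 by 1.68 ± 0.18 (3.2-fold, adjusted p = 2.6e-05), Bhmt by 1.52 ± 0.28 and Gzma by 1.47 ± 0.30. Limma called 1641 genes, 426 higher and 1215 lower, and 342 of them changed at least 1.5-fold. The split depended on scaling: 650 higher and 692 lower after repeated quantile normalization, and 893 higher and 506 lower with columns centred on their medians. The count was 955, 1020 or 1061 without control male 1, 2 or 3, and 833 without PAT male 2, and it was 1050 with the Gapdh difference as a covariate, 951 with only the groups compared and 2604 over single probe sets. Of 46 named genes that were called, 33 held whichever array was left out. Fgf15 (2.14 ± 0.64, adjusted p = 0.04) was lost in 6 of these 10 runs (up to 0.11, with a value of 1.51 without PAT male 5), and B3galt5 (-1.77 ± 0.56, adjusted p = 0.049) in all 10 (up to 0.11). Both also lost their calls with the Gapdh difference as a covariate, Fgf15 at 1.91 ± 0.73 (adjusted p = 0.14) and B3galt5 at -0.86 ± 0.49 (0.33).

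Among PAT males, endoplasmic reticulum stress genes ranked higher, with 8 of 13 higher, 0 lower and 5 not called (11 and 0 over the list alone). Chac1 rose by 1.73 ± 0.32, Dnajb9 by 1.13 ± 0.17, Trib3 by 0.75 ± 0.14 and Hspa5 by 0.54 ± 0.09, and the median was 0.472 (camera adjusted p = 3.44e-10, and 0.157 with an estimated correlation). Cholesterol synthesis genes ranked higher, with 8 of 20 higher, 0 lower and 12 not called (10 higher and 1 lower over the list alone). Insig1, which holds back the pathway's transcription factors, rose by 1.23 ± 0.18, Cyp51 by 0.69, Lss by 0.61 and Idi1 by 0.51, and the median was 0.327 (camera adjusted p = 1.45e-04, and 0.728 with an estimated correlation). Immediate early genes ranked higher, with 5 of 10 called higher and 0 lower (6 and 0 over the list alone), among them Dusp1 (1.44), Zfp36 (1.15) and Junb (0.77), and a median of 0.616 (camera adjusted p = 1.45e-04, and 0.679 with an estimated correlation). Dusp1 was lost in 8 of the 10 runs that each left out 1 array (adjusted p up to 0.082) and Junb in 5 (up to 0.079). The mean level of this list ran from -0.5 to 1.63 in PAT males and from -0.34 to 0.08 in control males, so the lowest PAT male lay below every control male. Of the bile acid genes 3 of 9 were higher and 0 lower (4 higher and 1 lower over the list alone), among them Abcc2 (1.78 ± 0.27), with a median of 0.346 (camera adjusted p = 0.00541, and 0.679 with an estimated correlation).

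Epithelial defence genes ranked lower in PAT males, with 6 of 17 lower, 1 higher and 10 not called (9 lower and 1 higher over the list alone). Reg3g fell by 0.65 ± 0.13 (adjusted p = 0.0048), Ccl28 by 0.66 ± 0.12, Pigr by 0.49 ± 0.09 and Saa2 by 1.63 ± 0.40, and Sprr1a rose by 2.27 ± 0.52. Retnlb (-2.91, adjusted p = 0.066) and Fut2 (-0.99, adjusted p = 0.054) did not pass. The median was -0.486 (camera adjusted p = 7.71e-04, and 0.679 with an estimated correlation). The stem cell list ranked lower, with 3 of 12 called lower, 0 higher and 9 not called (6 and 0 over the list alone): the crypt transcription factor Ascl2 (-0.85 ± 0.16), Znrf3 (-0.46) and Sox9 (-0.44), and a median of -0.272 (camera adjusted p = 7.12e-04, and 0.679 with an estimated correlation). Znrf3 and Sox9 were each lost in 4 of the 10 runs that left out 1 array (adjusted p up to 0.091 and 0.093). Of 19 xenobiotic metabolism genes 4 were lower and 0 higher (8 and 0 over the list alone): Cyp3a25 (-1.23 ± 0.30), Ces2a (-1.10 ± 0.27), Gsta3 (-0.51) and Gstt1 (-0.38), and a median of -0.323 (camera adjusted p = 0.0223, and 0.685 with an estimated correlation). That list call ended without PAT male 1 (0.054) or control male 5 (0.068), and Gstt1 was lost in 7 runs (up to 0.14) and Gsta3 without control male 3 (0.05). With the Gapdh difference as a covariate Cyp3a25 (-0.72 ± 0.25, adjusted p = 0.11), Ces2a (-0.79 ± 0.28, 0.11) and Saa2 (-1.0 ± 0.35, 0.11) had smaller folds and were not called. Gsta3 (-0.46 ± 0.15, 0.067), Gstt1 (-0.45 ± 0.13, 0.054) and Sox9 (-0.44 ± 0.14, 0.072) lost their calls with 91.3% or more of the log2 change kept. Of 7 Paneth cell genes 2 were lower and 0 higher, also over the list alone: Pla2g2a (-0.82), lost without control male 2 (0.052), and the protease Mmp7 (-0.54), lost in 7 of the 10 runs. The Paneth median was -0.344 (camera adjusted p = 0.0286, and 0.712 with an estimated correlation), a call that ended without PAT male 1 (0.091), PAT male 3 (0.11), control male 2 (0.066) or control male 4 (0.065).

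In females alone PAT raised Rab30 by 3.73 ± 0.43 (13.3-fold, adjusted p = 0.00024, 3 arrays against 3), Fst by 2.0 ± 0.29, Plat by 1.97 ± 0.30, the ERK phosphatase Dusp6 by 1.94 ± 0.29, Tcf23 by 1.76 ± 0.14 (adjusted p = 6.2e-07) and Dmp1 by 1.68 ± 0.29. G6pc fell by 2.61 ± 0.44 (6.09-fold, adjusted p = 0.0037) and Trim30d fell by 1.86 ± 0.29 (adjusted p = 0.0026). Saa1 fell by 3.91 ± 1.06 (15-fold, adjusted p = 0.046), with PAT levels spread over 7.48 ± 3.06 (SD), and its call was lost in 5 of the 6 runs that each left out 1 array (up to 0.22). Its value was -2.38 without PAT female 1, at an adjusted p of 0.22, and -5.43 without PAT female 2. Reg3g fell by 0.68 ± 0.17 (adjusted p = 0.033), a call lost in 3 runs (up to 0.17). Values for Saa2 (-1.64, adjusted p = 0.072), Retnlb (-2.80, adjusted p = 0.21, and -1.72 and -3.83 without PAT female 1 and 2) and Reg3b (-0.29, adjusted p = 0.11) did not pass. Limma called 610 genes, 413 higher and 197 lower, and 321 of them changed at least 1.5-fold. After repeated quantile normalization 361 were higher and 383 lower, and with columns centred on their medians 243 higher and 348 lower. The count was 243 without control female 1, 123 without control female 2 and 1 more than that without control female 3, and 133 or 180 without PAT female 1 or 2. With array weights it was 1524 and with a term for the title number 947. With the Gapdh difference as a covariate 102 genes were higher and 40 lower, and Saa1 (-3.06 ± 1.08, adjusted p = 0.17) and Reg3g (-0.55 ± 0.17, 0.13) were not called, with smaller folds. Of 30 named genes that were called, 8 held whichever array was left out: Rab30, Fst, Plat, Dusp6, Tcf23, Dmp1, G6pc and Trim30d.

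Interferon response genes ranked lower in PAT females, with 7 of 24 lower, 0 higher and 17 not called (13 and 0 over the list alone). Ifit1 fell by 2.29 ± 0.49, Oasl2 by 1.43 ± 0.34 and Rsad2 by 1.27 ± 0.30, and the median was -0.538 (camera adjusted p = 1.28e-08, and 0.734 with an estimated correlation). Of 20 cell division genes 2 were higher and 0 lower (16 and 0 over the list alone), the replication gene Mcm3 (0.91 ± 0.23) and the checkpoint kinase Bub1 (0.78 ± 0.20), and the median was 0.503 (camera adjusted p = 1.28e-08, and 0.734 with an estimated correlation). Of 8 endothelial genes 1 was higher, Kdr (0.71 ± 0.17), and 5 over the list alone, with a median of 0.503 (camera adjusted p = 1.47e-04, and 0.734 with an estimated correlation). Of 13 endoplasmic reticulum stress genes 2 were higher, Creld2 (0.77) and Manf (0.48), and 6 over the list alone, with a median of 0.381 (camera adjusted p = 8.45e-04, and 0.734 with an estimated correlation). These 4 list calls held whichever array was left out. Ifit1 was lost in 2 runs (adjusted p up to 0.089), Oasl2 in 4 (0.14), Manf in 6 (0.16), and Rsad2, Mcm3, Bub1, Kdr and Creld2 in 5 each (0.13, 0.14, 0.16, 0.15 and 0.16). Of these 8 genes only Ifit1 and Oasl2 were called with the Gapdh difference as a covariate. Mcm3 (0.81 ± 0.24), Bub1 (0.62 ± 0.21) and Kdr (0.58 ± 0.18) were smaller there, and Rsad2 (-1.38 ± 0.33), Manf (0.50 ± 0.14) and Creld2 (0.81 ± 0.23) were not.

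The B cell and follicle list had 1 of 14 members higher in PAT females, Cxcl13 (1.33, lost in 5 runs, and 0.62 with an adjusted p of 0.18 without PAT female 1), and 3 over the list alone, with a median of 0.428 (camera adjusted p = 0.0135, and 0.754 with an estimated correlation). The call ended without PAT female 1 (0.82) or control female 1 (0.069). No member was called of 9 genes of antigen presentation by MHC class II (median 0.426, camera adjusted p = 0.0279, and 0.803 with an estimated correlation), and that call ended without PAT female 1 (0.97) or control female 1 (0.07). No member was called of 13 tight junction genes (median -0.201, camera adjusted p = 0.0137, and 0.754 with an estimated correlation), a call that ended without PAT female 1 (0.063). No member was called of 15 macrophage and dendritic cell genes, and 2 higher and 1 lower over the list alone (median 0.304, camera adjusted p = 0.0491, and 0.754 with an estimated correlation), a call that ended without PAT female 1 (0.22), PAT female 2 (0.083) or control female 3 (0.21).

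**Figure D3:**
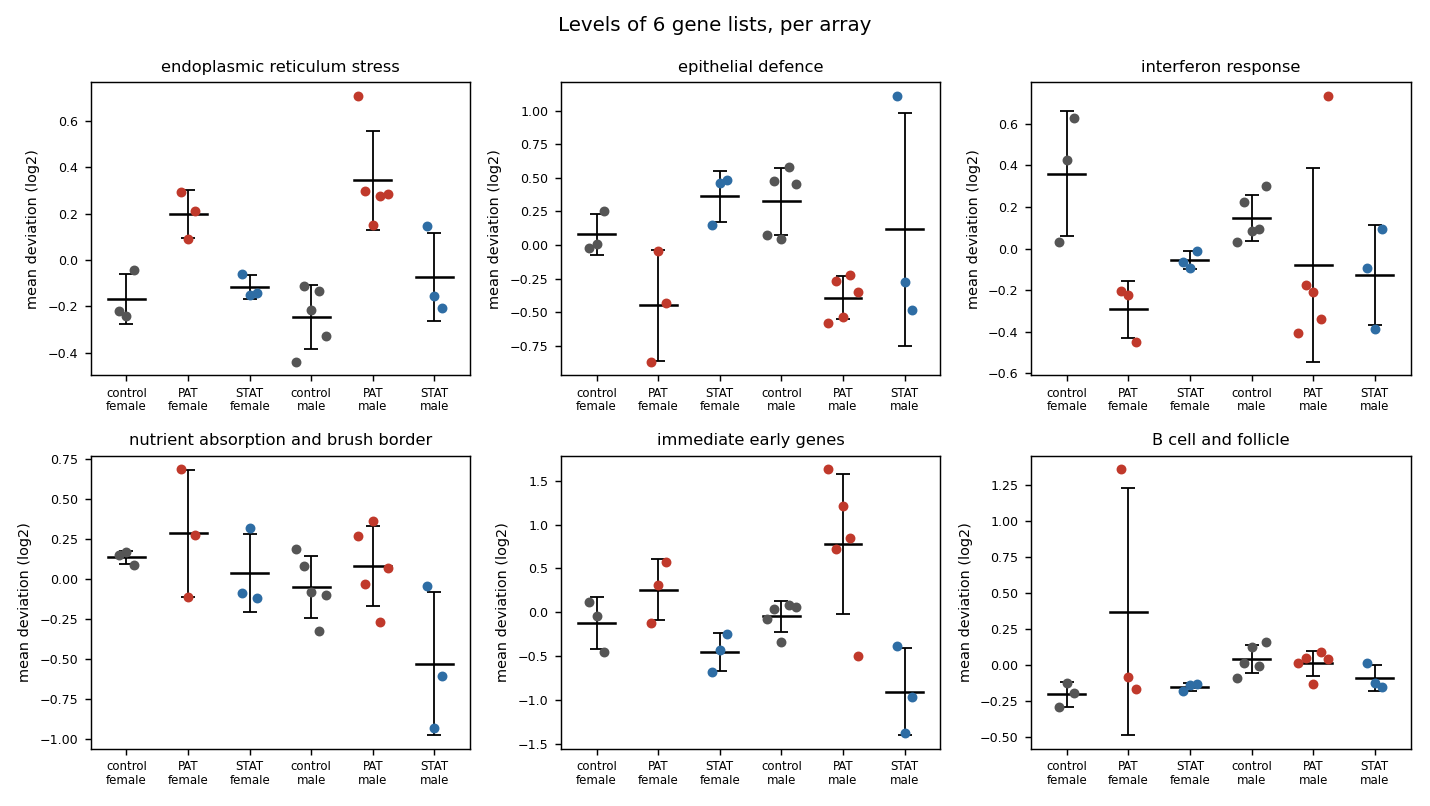
Level of 6 gene lists in each array, as the mean deviation of the members from their means over all arrays (log2). Points are arrays, lines are group means and bars are SD; groups hold 3 arrays, or 5 for control males and PAT males.

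The males and females compared share no arrays. PAT raised 84 genes in both sexes, against 9.67 expected of independent sets, and lowered 106, against 13.2 (Fisher's exact p = 7.46e-55 and 6.71e-72, with genes not independent of each other). Both comparisons take a gene's spread from the same fit, so a gene with a low estimate is called more readily in both. The expected numbers may therefore be too low and the p-values too small. Rab30, Dusp14 and Phlda1 are among the genes raised in both, and Saa1, G6pc and Reg3g among those lowered. The female calls of Dusp14 and Phlda1 ended in 4 and 3 of the 6 runs that left out 1 array (adjusted p up to 0.092 and 0.07), and Dusp14 in females was 1.95, and 1.31 without PAT female 3. The sexes differed in sign for 1 gene called in both. Of the male calls 1307 (79.6%) had the same sign in females, and of the female calls 491 (80.5%) had the same sign in males.

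The interaction test found 1 gene whose PAT effect differed between the sexes, the X-linked Fam122b (0.91 ± 0.14, adjusted p = 0.037). Its levels were 6.30 ± 0.18 (SD) and 6.82 ± 0.13 in control and PAT females, and 6.89 ± 0.10 and 6.5 ± 0.17 in males. Fam122b was lost in 10 of the 16 runs that left out 1 array (adjusted p up to 0.19, without PAT female 2), and the count rose to 59 without PAT female 3 and 50 without PAT male 5. It was 3 without PAT female 1 or PAT male 4, 2 without PAT male 2 or control male 5, and 0 otherwise. With array weights it was 165 and with columns centred 22. At an unadjusted p under 0.05 limma had 3383 genes. The next genes, Dmp1 (2.19, adjusted p = 0.055), Mnd1 (0.80), Galc (0.80) and 4930579G24Rik (1.14, adjusted p = 0.094), did not pass. Centring the columns moved the median of all genes from 0.029 to -0.13.

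No member of any list was called in the PAT interaction. Cell division genes ranked higher in the female effect (median 0.708, 13 higher and 0 lower over the list alone, camera adjusted p = 1.06e-08, and 0.698 with an estimated correlation), as did stem cell genes (median 0.454, 4 and 0 over the list alone, camera adjusted p = 5.57e-04, and 0.698). Cholesterol synthesis genes ranked lower (median -0.379, 0 over the list alone, camera adjusted p = 5.18e-05, and 0.698), and so did interferon response genes (median -0.29, 1 lower over the list alone, camera adjusted p = 0.00268, and 0.795). These 4 calls held whichever array was left out. Endothelial genes ranked higher (median 0.506, camera adjusted p = 0.00813), a call that ended without PAT female 1 (0.089). Macrophage genes ranked higher (median 0.465, camera adjusted p = 0.0216), a call that ended without PAT female 1 (0.069), PAT male 1 (0.083) or control female 3 (0.079). Neutrophil genes ranked lower (median -0.319, camera adjusted p = 0.0258), a call that ended without PAT female 3 (0.05) or control male 2 (0.054). Tight junction genes ranked lower (median -0.206, camera adjusted p = 0.0266) and Paneth cell genes higher (median 0.475, camera adjusted p = 0.0343), with 5 arrays ending the former call (up to 0.087) and 7 the latter (up to 0.11). The last 5 lists had an adjusted p of 0.698 with an estimated correlation.

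STAT males showed no gene that passed. The smallest p-values belonged to Chst8 (-0.70 ± 0.12), Arhgef2 (-0.52 ± 0.10), Dst (0.44 ± 0.08), Mtmr7 (-0.70 ± 0.14) and the chaperone Hsp90b1 (0.63 ± 0.13), all at an adjusted p of 0.11. Limma called 0 genes, with 2852 at an unadjusted p under 0.05. The count was 1973 without STAT male 1 and 3 without control male 4. With array weights, which were 0.316 for STAT male 1 and 2.82 for STAT male 3, it was 4069 (1682 higher and 2387 lower). None of the 17 epithelial defence genes passed, among them Saa1 (-0.96 ± 0.95), Retnlb (-0.81 ± 1.13) and Reg3g (-0.16 ± 0.15). The arrays went opposite ways: STAT male 1 lay above every control male (Saa1 13.4 and Retnlb 11.9), and STAT males 2 and 3 below the control means (10.51 and 8.87, and 6.82 and 4.73). Without STAT male 1 Saa1 was at -2.2 (adjusted p = 0.16) and Retnlb at -2.85 (0.052), and without STAT male 3 at 0.07 and 0.74.

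Brush border and nutrient absorption genes ranked lower in STAT males, with 21 of 22 members lower, 0 called and 14 lower over the list alone. The alkaline phosphatase Alpi (-0.75 ± 0.17), the apolipoprotein Apoa1 (-0.66 ± 0.16) and the peptidases Anpep (-0.76 ± 0.21) and Mep1b (-0.51 ± 0.13) led the list, which had a median of -0.501 (camera adjusted p = 4.63e-09, and 0.85 with an estimated correlation). Its mean differed from the control mean by -0.89 and -0.56 in STAT males 2 and 3, the arrays with the high actin difference, and by 0.00 in STAT male 1. Immediate early genes ranked lower, with 10 of 10 members lower and 2 over the list alone, among them Fos (-2.06 ± 0.50) and Junb (-0.87 ± 0.25), and a median of -0.742 (camera adjusted p = 3.57e-04, and 0.85 with an estimated correlation). Fos was at -2.74 without STAT male 1 (adjusted p = 0.0029) and at -1.33 without STAT male 2 (0.67). The same arrays differed by -1.32 and -0.92, and STAT male 1 by -0.33. Cell division genes ranked higher, 20 of 20 (median 0.261, camera adjusted p = 1.69e-05), as did smooth muscle genes, 11 of 11 with 1 over the list alone (median 0.262, camera adjusted p = 0.00254), and neuron and glia genes, 9 of 9 with 2 over the list alone (median 0.232, camera adjusted p = 0.00458, and 0.361 with an estimated correlation). Smooth muscle genes differed from control by 0.53 and 0.50 in STAT males 2 and 3 and by -0.11 in STAT male 1, cell division genes by 0.30, 0.49 and 0.06, and neuron and glia genes by 0.36, 0.33 and 0.11. These 5 calls held with any single array left out, and none of them held with an estimated correlation. Without STAT males 2 and 3 the group is STAT male 1 alone, which is assumed to vary like the other groups. None of the 5 was called then, and smooth muscle genes turned (adjusted p = 0.48, and 0.55 for brush border, 0.12 for immediate early, 0.63 for cell division and 0.43 for neuron and glia genes).

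The other lists called in STAT males each depended on single arrays. Endoplasmic reticulum stress genes ranked higher (median 0.164, 4 over the list alone, camera adjusted p = 0.00776), a call that ended without STAT male 1 (0.36). Interferon response genes ranked lower (median -0.288, 1 over the list alone, camera adjusted p = 0.00776), a call that ended without STAT male 1 (0.087) or STAT male 2 (0.14). Cytotoxic lymphocyte genes ranked lower (median -0.15, 5 over the list alone, camera adjusted p = 0.0156), a call that ended without STAT male 2 (0.07). Fibroblast genes ranked higher (median 0.368, camera adjusted p = 0.0157), a call that ended without STAT male 3 (0.15) or control male 1 (0.076). Xenobiotic metabolism genes, with Cyp3a11 at -2.44 ± 0.72, ranked lower (median -0.145, 2 over the list alone, camera adjusted p = 0.0239), a call that ended without STAT male 2 (0.42), STAT male 3 (0.13) or control male 5 (0.064). Cyp3a11 was at 7.58 and 7.99 in STAT males 2 and 3 and at 11.63 in STAT male 1, and its difference was -3.72 without STAT male 1 (0.0015) and -1.69 without STAT male 2 (0.68). With STAT male 1 as the only STAT male the xenobiotic list turned (0.034), a value from 1 array with the spread of other groups. Cholesterol synthesis genes ranked lower (median -0.165, camera adjusted p = 0.0225) and endothelial genes higher (median 0.232, 1 over the list alone, camera adjusted p = 0.0316), with 4 arrays ending the former call (up to 0.26) and 5 the latter (up to 0.15). With an estimated correlation every list call in STAT males was lost, with adjusted p from 0.361 to 0.98.

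STAT females showed no gene that passed. The smallest p-values belonged to Gm26553 (-0.44 ± 0.09), Pabpc2 (-0.65 ± 0.13), Snai2 (0.67 ± 0.14), Zfp759 (0.48 ± 0.11) and Gm36617 (-0.36 ± 0.08), all at an adjusted p of 0.83. Limma called 0 genes, with 602 at an unadjusted p under 0.05, and 0 whichever array was left out. Saa1 (1.03 ± 1.06), Retnlb (1.10 ± 1.26, and 1.69 without STAT female 1) and Reg3g (0.11 ± 0.17) did not pass. Interferon response genes ranked lower, 21 of 24, among them the GTPase Igtp (-1.06 ± 0.38) and Rsad2 (-0.82 ± 0.30), with a median of -0.346 (camera adjusted p = 2.28e-11, and 0.747 with an estimated correlation). Cholesterol synthesis genes ranked lower, 20 of 20, with a median of -0.161 (camera adjusted p = 6.58e-04, and 0.747 with an estimated correlation). Both calls held whichever array was left out. The interferon calls of PAT females, of STAT females and of females against males among controls share the same 3 control females. Their list level was 0.36 ± 0.3 (SD), from 0.03 to 0.63, so these calls are not independent of each other.

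Endothelial genes ranked higher in STAT females (median 0.238, camera adjusted p = 0.00719), a call that ended without STAT female 3 (0.19) or control female 3 (0.098). Bile acid genes (median -0.233), macrophage genes (0.144), smooth muscle genes (0.216) and T cell genes (-0.071) each had a camera adjusted p of 0.0301, and immediate early genes (-0.284) of 0.0387. These 5 calls ended in 3 or 4 of the 6 runs that left out 1 array, with adjusted p up to 0.26, 0.41, 1, 0.19 and 0.32 in the same order. No member of any list passed in STAT females, even over a list alone, and all these lists had an adjusted p of 0.747 with an estimated correlation.

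Averaged over the sexes, STAT left no gene past the test. The smallest p-values belonged to the transcription factor Zbtb16 (1.52 ± 0.28), Chst8 (-0.47 ± 0.09), Fkbp5 (0.53 ± 0.11), Hoxb3 (0.76 ± 0.15) and Aste1 (-0.35 ± 0.07), all at an adjusted p of 0.19. Limma called 0 genes, with 2391 at an unadjusted p under 0.05, and the count was 1053 without STAT male 1 and 2288 with array weights. Saa1 (0.03 ± 0.71, and -0.59 without STAT male 1) and Reg3g (-0.02 ± 0.11) did not pass. Interferon response genes ranked lower, 22 of 24 with 11 over the list alone (median -0.339, camera adjusted p = 1.7e-07, and 0.672 with an estimated correlation). Brush border genes ranked lower, 21 of 22 with 10 over the list alone (median -0.308, camera adjusted p = 1.7e-07, and 0.672, and not called in females, with a median of -0.094), and immediate early genes lower, 10 of 10 with 2 over the list alone (median -0.529, camera adjusted p = 2.33e-04, and 0.672). Cholesterol synthesis genes ranked lower, 20 of 20 (median -0.158, camera adjusted p = 4.25e-04, and 0.747). Smooth muscle genes (median 0.238, camera adjusted p = 4.25e-04, and 0.69) and endothelial genes (median 0.245, 2 over the list alone, camera adjusted p = 0.00236, and 0.672) ranked higher. These 6 calls held with any single array left out. Without STAT males 2 and 3, which leaves 1 STAT male, the brush border (0.15), cholesterol (0.24), smooth muscle (0.62) and endothelial (0.08) calls ended.

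The remaining list calls of STAT over both sexes ended with single arrays. Cell division genes (median 0.154, camera adjusted p = 0.00141) were not called without STAT female 3 (0.06), nor in females alone (median 0.02, camera adjusted p = 0.899). Fibroblast genes (median 0.269, camera adjusted p = 0.013) were not called without STAT female 3 (0.067), STAT male 3 (0.054) or control female 3 (0.14). Cytotoxic lymphocyte genes (median -0.117, camera adjusted p = 0.0147) were not called without control female 2 (0.054), and xenobiotic metabolism genes (median -0.12, camera adjusted p = 0.0147) without STAT male 2 (0.11). Endoplasmic reticulum stress genes (median 0.147, 4 over the list alone, camera adjusted p = 0.0156) were not called without STAT male 1 (0.29) or control female 1 (0.054). Bile acid genes (median -0.207, camera adjusted p = 0.0331), stem cell genes (median 0.134, camera adjusted p = 0.041) and neuron and glia genes (median 0.073, camera adjusted p = 0.041) were lost in 7, 8 and 7 runs (up to 0.095, 0.34 and 0.09). With an estimated correlation all of these were lost, with adjusted p from 0.672 to 0.747.

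No gene passed the test for a STAT effect that differed between the sexes, which had a median error of 0.171 over genes and cannot show that the effects are equal. The smallest p-values belonged to C1qtnf4 (0.82), Plppr5 (-0.74), Pabpc2 (-0.77), Zfp759 (0.58) and Klk1b11 (-0.55), all at an adjusted p of 0.99, and limma had 625 genes at an unadjusted p under 0.05. Brush border genes ranked higher in the female effect (median 0.414, camera adjusted p = 2.8e-05, and 0.907 with an estimated correlation). That call held with any single array left out, but without STAT males 2 and 3 the list turned (0.62). The male effect is then that of STAT male 1 alone, which differed from control males by 0.00. Cell division genes ranked lower, 20 of 20 (median -0.249, camera adjusted p = 1.59e-04, and 0.907), a call that ended without STAT female 2 (0.072). Neuron and glia genes ranked lower (median -0.271, camera adjusted p = 0.0131, and 0.471 with an estimated correlation), a call that ended without STAT female 3 (0.061). Epithelial defence genes ranked higher, 17 of 17 (median 0.269, camera adjusted p = 0.0424, and 0.907 with an estimated correlation), a call lost in 9 runs (up to 0.36).

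Compared with STAT males, PAT males had Rab30 higher by 4.77 ± 0.39 (27.4-fold, adjusted p = 8.7e-07, 5 arrays against 3), the transcription factors Egr1 by 3.27 ± 0.57 (9.67-fold) and Maff by 2.74 ± 0.32, Dusp14 by 2.94 ± 0.41 and the choline kinase Chka by 2.42 ± 0.28. The Egr1 value was 3.94 without PAT male 5. Edn2 was lower by -1.24 ± 0.21 (adjusted p = 0.0016), and the mucosal Dmbt1 by -1.08 ± 0.22. Limma called 1585 genes, 632 higher and 953 lower, and 609 of them differed at least 1.5-fold. After repeated quantile normalization 811 were higher and 795 lower, and with columns centred 854 higher and 551 lower. The count was 254, 300 or 2847 without STAT male 2, 3 or 1, and 879 without PAT male 2, and it was 4741 with array weights, 1016 with a term for the title number, 153 with only the groups compared and 2743 over single probe sets. Without STAT males 2 and 3 it was 62, a comparison with STAT male 1 alone, which is assumed to vary like the other groups. Of 49 named genes that were called, 15 held whichever array was left out, and leaving out STAT male 2 or 3 ended 32 or 26 calls. Saa1 (-3.11 ± 0.95, adjusted p = 0.045) and G6pc (-1.30 ± 0.39, adjusted p = 0.042) were lost in 6 and 7 of the 8 runs. The Saa1 value was -1.87 without STAT male 1 (adjusted p = 0.2) and -4.14 without STAT male 3 (0.042).

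Immediate early genes ranked higher in PAT males than in STAT males, with 8 of 10 higher, 0 lower and 2 not called, also over the list alone. Junb differed by 1.64 ± 0.25 and Zfp36 by 1.83 ± 0.33, and the median was 1.734 (camera adjusted p = 3.01e-09, and 0.516 with an estimated correlation). Of 22 brush border genes 7 were higher and 0 lower (11 and 0 over the list alone), among them Apoa4 (2.34 ± 0.49), Apoc3 (1.49 ± 0.35) and Alpi (0.77 ± 0.17), with a median of 0.424 (camera adjusted p = 1.18e-08, and 0.517 with an estimated correlation). Of 20 cholesterol synthesis genes 11 were higher and 0 lower (15 and 0 over the list alone), among them Insig1 (1.25 ± 0.20) and Sqle (0.80), with a median of 0.539 (camera adjusted p = 3.56e-08, and 0.517). Of 9 bile acid genes 4 were higher and 0 lower (6 higher and 1 lower over the list alone), among them Abcc2 (2.15 ± 0.31), with a median of 0.699 (camera adjusted p = 4.01e-04, and 0.517). Of 13 endoplasmic reticulum stress genes 4 were higher and 0 lower (5 and 0 over the list alone), among them Dnajb9 (0.97 ± 0.20) and Trib3 (0.82 ± 0.16), with a median of 0.233 (camera adjusted p = 9.82e-04, and 0.517). Junb, Zfp36, Insig1 and Abcc2 were called whichever array was left out. Apoa4, Sqle and Trib3 were lost without STAT male 2 (adjusted p = 0.064, 0.058 and 0.065), with Apoa4 at 1.39 there and at 3.13 without STAT male 1, Dnajb9 without STAT male 3 (0.052), and Apoc3 and Alpi in 2 runs each (up to 0.13 and 0.12).

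Of 20 cell division genes 7 were lower in PAT males than in STAT males and 0 higher (13 and 0 over the list alone), among them Kif11 (-0.89 ± 0.18) and Mki67 (-0.77 ± 0.20), with a median of -0.412 (camera adjusted p = 3.01e-06, and 0.543 with an estimated correlation). Of 12 stem cell genes 3 were lower and 0 higher (10 and 0 over the list alone), among them Ascl2 (-0.96 ± 0.18), with a median of -0.464 (camera adjusted p = 1.26e-05, and 0.517). Of 11 smooth muscle genes 1 was lower, the myosin Myh11 (-0.78 ± 0.22), and 10 over the list alone, with a median of -0.55 (camera adjusted p = 1.16e-04, and 0.543). Of 8 fibroblast genes 2 were lower, Lum (-0.74) and Col1a2 (-0.72), and 4 over the list alone, with a median of -0.488 (camera adjusted p = 0.00279, and 0.543). Of 17 epithelial defence genes 4 were lower and 1 higher (5 and 2 over the list alone), among them Ccl28 (-0.64 ± 0.13) and Pigr (-0.41 ± 0.10), with a median of -0.414 (camera adjusted p = 0.0208, and 0.641). The epithelial defence call ended without STAT male 1 (0.58) or PAT male 1 (0.062), and the other 9 list calls held with any single array left out. Against STAT male 1 alone, assumed to vary like the other groups, the stem cell list turned (0.93), its level in STAT male 1 being -0.28 from control against 0.31 and 0.32 in the pair, and the brush border (0.32), bile acid (0.2), endoplasmic reticulum stress (0.26), cell division (0.26), smooth muscle (0.82) and fibroblast (0.74) calls ended. Ascl2 was called whichever array was left out, Ccl28 was lost without STAT male 2 (0.062), Kif11 and Pigr were lost in 2 of the 8 runs (up to 0.066 and 0.12), Mki67 in 3 (0.16), Myh11 and Lum in 5 (0.18 and 0.19) and Col1a2 in 6 (0.25).

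Compared with STAT females, PAT females had Rab30 higher by 3.78 ± 0.43 (13.7-fold, adjusted p = 0.00013, 3 arrays against 3), Dusp6 by 1.96 ± 0.29, Tcf23 by 1.77 ± 0.14 (3.4-fold, adjusted p = 5.9e-07) and Phlda2 by 1.72 ± 0.18 (adjusted p = 5e-05). G6pc was lower by -2.68 ± 0.44 (6.41-fold), Saa2 by -2.27 ± 0.51, the iron exporter Slc40a1 by -1.52 ± 0.29 and Reg3g by -0.79 ± 0.17. Saa1 was lower by -4.93 ± 1.06 (30.6-fold, adjusted p = 0.029), a call lost in 5 of 6 runs (up to 0.14), as were those of Saa2 (0.16) and Reg3g (0.15), and Slc40a1 was lost in 2 (0.068). The Saa1 value was -3.41 without PAT female 1 (adjusted p = 0.12) and -6.46 without PAT female 2 (0.0038). Limma called 157 genes, 96 higher and 61 lower. The share that was higher was 61.1%, against 48.7% after repeated quantile normalization and 50% (90 higher and 90 lower) with columns centred. The count was 80, 82 or 86 without PAT female 1, 2 or 3, and 43 or 29 without STAT female 1 or 2. It was 640 with array weights, 606 with a term for the title number and 43 with only the groups compared. Of 21 named genes that were called, 7 held whichever array was left out.

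Cell division genes ranked higher in PAT than in STAT females, with 0 of 20 called and 13 higher over the list alone (median 0.522, camera adjusted p = 5.58e-10, and 0.606 with an estimated correlation). Epithelial defence genes ranked lower, with 3 of 17 called lower, 0 higher and 14 not called (5 and 0 over the list alone, median -0.337, camera adjusted p = 4.42e-04, and 0.606). The 3 were Saa1, Saa2 and Reg3g, each lost in 5 of 6 runs. Endoplasmic reticulum stress genes ranked higher with 0 called (median 0.298, camera adjusted p = 0.00176, and 0.606). These 3 list calls held whichever array was left out. Bile acid genes (median 0.384, 4 higher over the list alone, camera adjusted p = 0.00494, and 0.606) and immediate early genes (median 0.53, 3 higher over the list alone, camera adjusted p = 0.00494, and 0.788) were not called without PAT female 3 (0.12 and 0.071).

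B cell and follicle genes (median 0.435, 1 higher over the list alone, camera adjusted p = 0.00606, and 0.799 with an estimated correlation) and tight junction genes (median -0.179, camera adjusted p = 0.0101, and 0.788) were not called in this comparison of females without PAT female 1 (0.94 and 0.061). Endothelial genes (median 0.292, 1 higher over the list alone, camera adjusted p = 0.0161, and 0.788) were not called without PAT female 1 (0.32) or STAT female 2 (0.12), and interferon response genes (median -0.233, camera adjusted p = 0.0301, and 0.841) without PAT female 3 (0.27) or STAT female 3 (0.086). Smooth muscle genes (median -0.296, camera adjusted p = 0.0091, and 0.841) were lost in 3 runs (up to 0.26). MHC class II genes (median 0.253, camera adjusted p = 0.0366, and 0.841) and the fatty acid and triglyceride synthesis genes (median 0.111, 3 higher over the list alone, camera adjusted p = 0.0373, and 0.606) were lost in 4 runs each (up to 0.52 and 0.12).

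Among controls, Xist was higher by 5.59 ± 0.28 (48.3-fold) and the X-linked demethylase gene Kdm6a by 0.62 ± 0.09, and the Y-linked Eif2s3y (-5.51 ± 0.13), Kdm5d (-5.03 ± 0.12) and Uty (-4.25 ± 0.13) were lower in females than in males. Limma called 10 genes, 5 higher and 5 lower, of which 3 lie on the Y chromosome, 3 on the X and 4 elsewhere. The latter were Stxbp5l (0.82), 4933406K04Rik (0.62), Gm26553 (0.47) and Ube2d1, and 2283 genes had an unadjusted p under 0.05. The count was 63, with 58 higher and 5 lower when columns were centred on their medians. The count was 17 without control female 1, 332 with array weights, 19 with the mean of a gene's probe sets and 71 over single probe sets. Fam122b, on the X, was lower by -0.60 ± 0.10, a call that ended without control female 2 (adjusted p = 0.19) or control male 3, and Ube2d1 (-0.55 ± 0.10) was lost in 7 of 8 runs (up to 0.19). The sex check list had a camera adjusted p of 1.02e-13, and 0.000247 with an estimated correlation. Macrophage and dendritic cell genes ranked lower in females (median -0.292, 5 lower over the list alone, camera adjusted p = 1.16e-04, and 0.435 with an estimated correlation), as did plasma cell genes (median -0.346, 3 lower over the list alone, camera adjusted p = 0.00242, and 0.35), and both calls held whichever array was left out. Cholesterol synthesis genes (median 0.136, camera adjusted p = 0.0219, and 0.929) and interferon response genes (median 0.18, camera adjusted p = 0.0373, and 0.929) ranked higher, calls lost in 4 and 5 runs (up to 0.18 and 0.58).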

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

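The groups, comparisons and lists were fixed before the data were examined. The tests below were chosen only after these results were seen. The criteria for the covariates, the slopes on actin and Gapdh, the villus tip genes, the epithelium over follicles and the splits of arrays were written before those values were computed, and that for the epithelium as a whole was written after. The epithelium test first used Paneth, goblet and enteroendocrine genes and decided nothing, with Paneth genes at 0.17 and 0.1 against a control SD of 0.21. Its criterion was then changed to the stem cell list. A first test of PAT female 1, the B cell median without it, restated the pattern and was replaced, and the Gapdh tests were added last. The search for arrays far from their group was narrowed to the largest rises and falls of 3 comparisons and 4 measures of the arrays.

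The 10 largest rises of PAT mice over both sexes include Egr1, an immediate early gene, so uneven tissue handling was weighed as a candidate explanation. With the mean of 9 immediate early genes as a covariate, 10 of the 10 genes stayed called, with a median of 1.73 against 1.88 without it, and Egr1 moved from 1.79 to 0.92. With the actin difference as a covariate 10 of the 10 stayed called, with a median of 1.98, and with the Gapdh difference, which is higher with PAT in both sexes, 9 did, with a median of 2.21. The Fgf15 call ended (2.16 ± 0.52 before and 1.93 ± 0.64 after), because the fold shrank and its error grew. With the immediate early covariate Fgf15 and Fst moved up (2.67 and 1.87) and the others down, among them Phlda1 (1.93 to 1.5), Flrt3 (1.87 to 1.47) and Maff (1.75 to 1.33). The actin difference hardly differed between PAT and control, at 0.34 ± 0.06 (SD) and 0.32 ± 0.04 in males and 0.37 ± 0.05 and 0.33 ± 0.01 in females. Its covariate could therefore hardly end a call, and that result decides nothing. The calls that stayed with the immediate early and the Gapdh covariate argue against handling and RNA integrity, as read from these 2 measures, as the sole source of the 9 rises. Handling stays possible as part of the values that shrank with its covariate. Integrity stays possible as part of Fgf15, Plat and Fst, which shrank with the actin and the Gapdh difference (1.93, 1.78 and 1.66 with Gapdh).

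STAT males 2 and 3 stand apart from STAT male 1 and the other arrays, with lower brush border genes and higher smooth muscle genes (0.53 and 0.5 above the control males). Over genes, the slope on the actin difference within the other 20 arrays correlated with the differences of the 2 arrays at 0.5 and 0.54 (permutation p = 0.004 and 0.001), which fits lower RNA integrity, and the same test on Gapdh decided nothing, at 0.28 and 0.29 (permutation p = 0.1 for both). The stem cell list lay 0.31 and 0.32 higher against a control SD of 0.07, where an even loss of all epithelial cells would lower it. This criterion was chosen after the first lists had decided nothing, so it is no test of such a loss. Nor can it exclude a loss of part of the epithelium, because the list covers stem cells only. Fibroblast genes were 0.39 and 0.56 higher in the 2 arrays, and neuron and glia genes 0.36 and 0.33. Fewer villus tip cells stay possible, with a median of -1.5 and -1.22 for 5 measured villus tip genes against 0.19 in STAT male 1, and Ada at -3.56 and -3. Integrity, villus tip cells and a loss of epithelium, even or in part, all stay open.

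The higher B cell and MHC class II genes of PAT females rest on PAT female 1. Its B cell and follicle level was 1.358 against at most 0.156 in any other array, and Ms4a1, a B cell surface gene, was at 9.16 in it. The median of the B cell and follicle list was 0.43 with the array and 0.02 without it, and that of MHC class II 0.43 and -0.02. These values show that 1 array carries the change, with PAT females 2 and 3 at -0.085 and -0.169, and not what its source is. A lymphoid follicle in that piece of tissue is a candidate source that stays open: 8 genes of the epithelium over follicles had a median of 0.07, with Clu at 2.11 and Gp2 at 1.54 and others lower than in controls.

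Whether chance could give the counts was tested by counting called genes in other splits of the same arrays. Chance is unlikely for PAT males, where 1 of 100 splits, the real one, reached 1641 genes and the highest other had 498. It is also unlikely for PAT over both sexes (1 of 100, 1999 against 8). In both comparisons only part of the possible splits was drawn, and 1 of 100 is the smallest share this test can give. Chance is therefore not strictly excluded in either. For female against male controls (1 of 56, 10 against 4) the sex-linked genes among the 10 follow the real split only. That result was fixed in advance and says nothing about the other calls. For PAT against STAT males 2 of 56 splits reached the real count of 1585, and exchanging STAT male 1 with PAT male 4 gave 2461, which points to the structure of the STAT males. Chance could well give the count of the PAT interaction (8 of 100, 1 against 311, a count that also points to a structure of the samples). A real count of 0 is reached by any split, so the test says nothing about chance for STAT males (56 of 56), STAT females (10 of 10), STAT over both sexes (100 of 100) and the STAT interaction (100 of 100), where the highest other splits had 1108, 1, 4 and 8 genes. The 1108 came from exchanging STAT male 1 with control male 4, again a structure of the samples. The splits are too few in females, with 610 against 0 for PAT (1 of 10) and 157 against 1 for PAT against STAT (1 of 10).

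Of 86 cases of a gene or measure in a group of 5 arrays, 2 (2.33%) had an array far from the rest, and chance gives about 1 in 20. Dusp14 in control males had a gap ratio of 0.747 against a critical value of 0.71, with control male 3 at 6.53 and the others at 5.91 to 6.07. Phlda1 in PAT males had a gap ratio of 0.885, with PAT male 5 at 9.33 and the others at 11.17 to 11.41.

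The PAT effect differed between the sexes by 0.91 for Fam122b. The mean difference of the called lists was 0.67 for cell division, -0.37 for cholesterol synthesis, 0.47 for endothelium, -0.43 for interferon response, 0.35 for macrophage and dendritic cell genes, -0.23 for neutrophil genes, 0.46 for Paneth cell genes, 0.44 for stem cell genes and -0.22 for tight junctions. For STAT it was -0.25 for cell division, -0.22 for neurons and glia, 0.49 for epithelial defence and 0.38 for brush border genes.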

How the results depend on the processing

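The alternatives were chosen before the data were examined, except the runs without pairs of arrays, the actin and Gapdh covariates and the list tests with 1 array left out, which were chosen after seeing the data. No paired analysis was possible because no 2 arrays share a number in the labels. Of 4421 comparisons of 199 named calls with another setting, 3677 were the same, 744 lost the call and 0 reversed. Of 8736 such comparisons of genes named without a call, 8425 were the same and 311 gained a call.

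Counts of called genes moved as follows. With the mean of a gene's probe sets the female against male controls gave 19. With every probe set tested PAT males gave 2604, STAT males 1, PAT over both sexes 3287, STAT over both sexes 1, the PAT interaction 0, PAT against STAT males 2743 and controls 71. Repeated quantile normalization gave 0 for the PAT interaction. Centred columns gave 22 for the PAT interaction and 63 for controls. With only the groups compared PAT males gave 951, STAT over both sexes 1, the PAT interaction 0, PAT against STAT males 153 and females 43. A trend with robust estimation gave 0 for the PAT interaction.

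Array weights gave 1524 for PAT females, 4069 for STAT males, 2288 for STAT over both sexes, 165 for the PAT interaction, 4741 for PAT against STAT males, 640 for females and 332 for controls. In STAT males they gave STAT male 1 a weight of 0.316 and STAT male 3 of 2.82. A term for the title number gave 947 for PAT females, 0 for the PAT interaction, 1016 for PAT against STAT males and 606 for females. At least 1.5-fold left 342 for PAT males, 321 for PAT females, 323 over both sexes and 609 for PAT against STAT males.

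Leaving out 1 array gave 833 to 2089 genes for PAT males, 123 to 751 for PAT females, 1353 to 2494 over both sexes and 0 to 59 for the PAT interaction. STAT gave 0 to 1973 in males, 0 in females, 0 to 1053 over both sexes and 0 for the interaction. PAT against STAT gave 254 to 2847 in males and 29 to 118 in females, and controls 7 to 17.

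Without PAT female 1 and PAT male 5, PAT females gave 228 genes and the PAT interaction 6. MHC class II genes then turned, with an adjusted p of 0.96 in PAT females and 0.5 against STAT females. Leaving out STAT males 2 and 3 leaves STAT male 1 as the only STAT male, assumed to vary like the other groups. STAT males then gave 9 and PAT against STAT males 62. Lists that then turned were, in STAT males, cholesterol synthesis (adjusted p = 0.54), fibroblast (0.7), smooth muscle (0.48) and xenobiotic metabolism (0.034), over both sexes stem cell (0.075) and xenobiotic metabolism (0.55), in the STAT interaction epithelial defence (0.061) and brush border (0.62), and in PAT against STAT males stem cell (0.93). With the actin covariate PAT gave 2146 genes in males, 692 in females and 2084 over both sexes, and STAT 0 in each. With the Gapdh covariate PAT gave 1050 in males, 1.4e+02 (102 higher and 40 lower) in females and 756 over both sexes, and STAT 0 in each. The median size of the 1999 changes over both sexes moved from 0.35 to 0.30 and their errors grew 1.19-fold.

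Of 98 list calls, 92 held with centred columns, 93 with the mean of probe sets, 10 with fry and 1 with an estimated correlation, and 79 of 97 with bright genes only. Without PAT female 1 and PAT male 5, 42 of 55 held, and without STAT males 2 and 3, 8 of 40.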

Other observations

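The only test added in this part, that of glucocorticoid induced genes, was chosen after Zbtb16 and Fkbp5 had been seen among the STAT results, and its list and criterion were written before its values were computed. Of the gene lists fixed beforehand, 12 were not called in any comparison. Circadian clock genes came nearest, with a smallest camera adjusted p of 0.0564 and medians from -0.113 to 0.202. Within that list PAT over both sexes left 5 of 18 genes higher and 3 lower (6 and 4 over the list alone), so its members moved in both directions. Cell types of the epithelium that were never called were goblet cells (0.101, medians from -0.073 to 0.041), enteroendocrine cells (0.236, -0.096 to 0.19) and tuft cells (0.157, -0.104 to 0.139). Among immune cells these were mast cells (0.35, -0.115 to 0.073), regulatory T cells (0.522, -0.034 to 0.166) and type 17 lymphocytes (0.493, -0.055 to 0.12). Fatty acid oxidation genes (0.106, -0.046 to 0.122) and the lists for tissue carried along, namely adipocyte (0.472, -0.387 to 0.613), colon (0.403, -0.193 to 0.101), pancreatic acinar cell (0.662, -0.091 to 0.199) and red blood cell (0.154, 0.002 to 0.357), were not called either. Adipocyte levels varied widely within groups, from -1.46 to 2.23 in control males and from -1.78 to 1.64 in PAT females. That this list was not called therefore does not show that the samples held equal amounts of fat.

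Fgf15 was highest in PAT female 1 (11.36) and PAT male 5 (11.08), the arrays that stand apart from their groups, and between 7.38 and 8.92 in the other PAT arrays. Egr1 and Phlda1 were lowest in PAT male 5 among PAT males, at 9.66 and 9.33. This Egr1 level also lay below every control male (9.91 to 10.51). Among members of lists not called in PAT over both sexes, cytotoxic lymphocyte genes had 3 of 12 lower and 0 higher (5 and 0 over the list alone, camera adjusted p = 0.0529), xenobiotic metabolism genes 4 of 19 lower and 0 higher (6 and 0, camera adjusted p = 0.0693), and cholesterol synthesis genes 4 of 20 higher and 2 lower (7 and 3, camera adjusted p = 0.106).

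Zbtb16 and Fkbp5, both induced by glucocorticoids, were among the smallest p-values of STAT over both sexes without passing. A higher glucocorticoid response in STAT mice could raise both. Of 10 other glucocorticoid induced genes 4 were higher, with a median of -0.28 and values from -0.69 to 0.26. The negative median met the criterion set against this explanation. No gene of the 10 passed (limma adjusted p from 0.22 to 0.63). The values therefore show no broad rise of such genes, but they cannot exclude a glucocorticoid response.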
